A study of Priestia endophytica with 2 samples.

How the data were processed

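RNA came from colonies of Priestia endophytica FH5 started from 5 µl of cells beside an agar plug, with or without a 0.5 cm plug of Rhizoctonia solani mycelium. Per the labels' protocols, 800 ng of total RNA went into a kit that removes ribosomal RNA (Zymo-Seq RiboFree), and the libraries were read on an Illumina NextSeq instrument as single-end reads of 75 bases, at a stated average depth of 12M reads. The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.4.2 and SAMtools 1.11. The counting program, its strand setting, the genome build and the annotation are not given in the sources used here. Without a known strand setting, reads of overlapping features cannot be assigned with certainty, and 581 of the 5546 features overlap a neighbour.

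Each library has a table with a contig, start, end, strand and length per feature. Per the file headers, the authors deposited a whole-number count of reads per feature, the reads per kb, and an RPKM. The reads per kb equalled the count divided by the length in kb in all 5546 rows, within 0.0051. The deposited RPKM was the reads per kb divided by a constant, 1783000 reads in the untreated and 2162000 reads in the exposed library. The total count was 3.85 and 2.13 times these constants, and what the constants count is not stated. A constant of this kind is removed when ratios are centred on the median feature, so the main ratios do not depend on it apart from the pseudocount. Of the features, 5488 (99.0%) had lengths in multiples of 3, so lengths of these are taken as coding lengths. The other 58, among them the features of contigs 34 and 39, held 6.20% of the counts in untreated cells (exact Clopper-Pearson interval 6.19 to 6.22) and 4.02% (4.00 to 4.04) in exposed cells. There were 20 features shorter than the read length. Contig numbers are the final digits of the sequence names in the tables.

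The main value was log2 of (exposed RPKM + 1) over (untreated RPKM + 1), less its median (0.07) over the kept features. Features were kept with a mean RPKM of at least 5 and at least 20 reads over both libraries, which left out 62. With 1 library per group no p-value, standard error or test of the difference between conditions was computed; shuffles, random lists and bootstrap intervals describe features within these 2 libraries. Features at a log2 ratio of 1 and 2 or beyond were counted as 2-fold and 4-fold. The fold of a named feature or run is the ratio of its reads, scaled by the same centre, with an exact 95% Clopper-Pearson interval for the share of its reads that came from the exposed library. These reads have no molecular identifiers, so such intervals and the limits for a count of 0 (3 counts of the total) cover counting error only. Across kept features the log2 RPKM of the 2 libraries had a Pearson r of 0.917, and features are not independent replicates.

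These ratios, thresholds, filters, alternative settings and the naming rule were fixed before the data were examined, as were 33 gene lists for functions such as sporulation, motility, secondary metabolites and stress. Because the tables give neither symbols nor products, 0 features could be matched, none of the lists was applied, and features of RNA genes could not be left out. The naming rule asked for the 15 highest and 15 lowest named genes, members of lists, the 10 genes of highest mean RPKM, and 3 unnamed genes at each end. Only the last 2 parts could be used, with 2 identifiers per direction among features with a mean RPKM of at least 20. The 12 lowest features, the highest with at least 100 untreated reads, the runs and the contigs were chosen for description after the values were seen.

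The following were also added after the data were examined. Level-matched ratios are centred on the median within each of 20 groups of mean RPKM. A run is 4 or more neighbouring features on 1 contig and strand, at most 100 bases apart, each at least 2-fold in the same direction, and 1000 shuffles of the ratios within the 20 levels gave its reference. A contig median was placed among 10000 random lists of the same size matched on the 20 levels, and stood apart below percentile 2.5 or above 97.5. The 5th and 10th percentiles of reads per kb over features of 300 nt or more describe the low end of each library.

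Code used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with fixed seeds. It was tested on simulated data for the exposed against untreated comparison, with Poisson counts for 5488 kept features, of which 200 were changed. All 40 features changed at each of 4-fold and 8-fold higher and 4-fold and 8-fold lower were called at 2-fold (100.0%), as were 32.5% of those changed by exactly 2-fold. Of 5288 unchanged features 11 were called, and intervals held the true fold for 93.0% of changed features on average. Both simulated libraries came from 1 shared profile, with no difference in floor and no trend of the ratio with level. The simulation therefore checks the code, and does not tell how many 2-fold calls in the real libraries are false.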

Results

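Priestia endophytica strain FH5, a spore-forming soil and plant bacterium, was grown for 3 days at 28 °C on potato dextrose agar, 2 cm from an agar plug that either carried Rhizoctonia solani, a fungal plant pathogen, or carried no fungus. Total RNA of the bacterium was depleted of ribosomal RNA and sequenced, with 1 library of untreated cells and 1 library of cells exposed to the fungus. The deposited tables listed 5546 annotated features on 45 contigs of a draft genome. The total count over these features was 6872325 in the untreated library and 4610596 in the exposed library. A median feature had 253 reads in the untreated library and 364 in the exposed library, and 19 and 10 features respectively had none, for which a count of 0 allowed up to 0.437 and 0.651 CPM.

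The question was which transcripts of the bacterium differed in abundance when the fungus grew nearby. With 1 library per group no difference below has a replicate check. Each describes these 2 libraries, not the conditions. Intervals are exact 95% counting intervals and cover counting error only. Ratios were set relative to the median of the 5484 features kept. The files do not pair the feature identifiers with gene names or products, so transcripts are given by contig and coordinates, and no gene function is stated.

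The largest difference was a pair of adjacent features on the minus strand of contig 9 that were strongly expressed in untreated cells and far lower in exposed cells. FH5_05407 (contig 9, 4770 to 6395) had an RPKM of 13036 in the untreated library and 468 in the exposed library, a level 29.2-fold lower (27.8 to 30.7). Its neighbour FH5_05408 (contig 9, 6419 to 7375) went from 50754 to 2439 RPKM, 21.8-fold lower (21.2 to 22.5), and in untreated cells only 1 feature, on contig 39, had a higher RPKM. On the higher side the extremes were short features with few reads. FH5_05289 (contig 8, 33158 to 33229), 72 nt long and thus shorter than a 75-base read, had 1 read in the untreated library and 20 in the exposed library, a ratio of 15.7 (2.51 to 651). FH5_01693 (contig 10, 69524 to 69640) had 3 and 47 reads, a ratio of 12.3 (3.96 to 61.8).

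Among the 12 features with the lowest ratios, 4 pairs were direct neighbours on the same strand. Besides the pair on contig 9, the features at 405590 to 405910 and 405924 to 408335 of contig 1 were 17.3-fold (15.2 to 19.8) and 11.3-fold (10.7 to 11.9) lower in the exposed library. Those at 391296 to 392246 and 392324 to 392467 of the same contig were 9.17-fold (8.88 to 9.47) and 10.3-fold (9.44 to 11.3) lower, from RPKM values of 17975 and 17540 in untreated cells. On contig 4, the overlapping features at 166452 to 167516 and 167513 to 168085 were 8.78-fold (8.09 to 9.54) and 9.97-fold (9.14 to 10.9) lower. A single feature of 204 nt on contig 4 (221598 to 221801) was 18.7-fold lower (16.0 to 21.9), and features on contig 3 (168096 to 169082), contig 2 (547888 to 549159) and contig 1 (561906 to 562241) were 10.3-fold, 9.43-fold and 9.07-fold lower. Against features of the same level the 12 differed less, with log2 ratios between -3.66 and -1.94. Scaled to the total count these lay between -3.95 and -2.21.

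Of the features with at least 100 reads in the untreated library, the highest ratio belonged to a feature on contig 30 (12095 to 12751, plus strand), which had 172 reads in the untreated and 1466 in the exposed library and was 6.69-fold higher (5.71 to 7.89) in the exposed library. A group of 3 consecutive features on the minus strand of contig 1 (1467336 to 1470363) was higher together, at 3.55-fold (3.29 to 3.83), 2.04-fold (1.80 to 2.31) and 4.07-fold (3.50 to 4.76) in the order of their coordinates. These 4 features had RPKM values between 147 and 981 in untreated cells, well above the level at which most of the higher features lay.

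Over all kept features, 1096 were at least 2-fold higher in the exposed library and 907 at least 2-fold lower. At 4-fold, 32 were higher and 103 lower. The counting interval lay wholly beyond 2-fold for 366 features on the higher side and 701 on the lower side. The 2 sets came from opposite ends of the expression range. The median RPKM of the higher features was 57.5 in the untreated library and 151 in the exposed library, while that of the lower features was 1664 and 642. By mean RPKM of both libraries, the 549 lowest features held 322 of the higher and 0 of the lower features, and the 549 highest held 1 and 381. In untreated cells 998 of the 1096 higher features (91.1%), and 127 of the 136 in runs of higher neighbours, lay under 2 times the 10th percentile of reads per kb, as did 33.6% of all kept features and 0 of the lower ones. The untreated level is the denominator of the ratio, which by itself favours such a difference. The median centred log2 ratio went from 1.10 in the 549 lowest to -1.22 in the 549 highest. Relative to features of the same expression level, 265 features were at least 2-fold higher and 208 lower, and these included 192 of the 1096 and 122 of the 907.

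**Figure D1:**
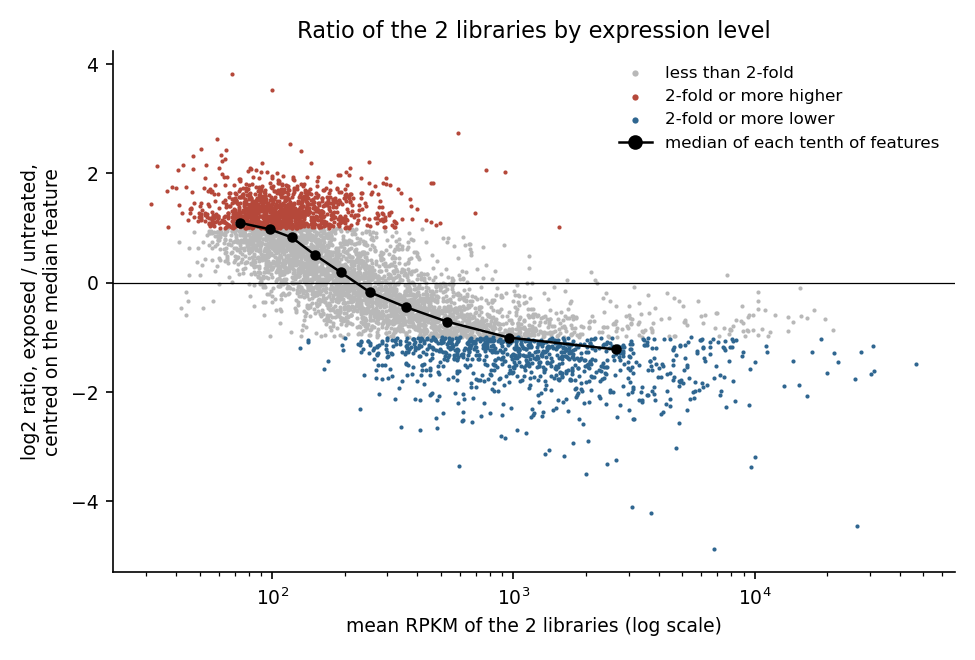
Each point is 1 of 5484 kept features, with the mean RPKM of the 2 libraries on the horizontal log axis and the log2 ratio of exposed to untreated, centred on the median feature, on the vertical axis; red and blue points are at least 2-fold higher and lower, and black points are medians of 10 groups of equal size by level. The medians go from 1.10 at a mean RPKM near 73.3 to -1.22 near 2654, so the red points lie at the low and the blue points at the high end of expression.

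The balance between higher and lower features depended on the scaling. Scaled to the total count of each library, the median feature was 0.89 log2 units higher in the exposed library, and 2566 features were at least 2-fold higher against 123 lower. With the RPKM values rescaled to the same sum, the split was 2588 against 130, and without the top 1% of features it was 2432 against 149. The deposited RPKM values without centring gave 1229 against 785. At 4-fold the larger side changed: 699 features were higher and 15 lower by total count, 903 and 15 at the same sum, and 17 and 14 relative to features of the same level.

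The 10 features with the most reads in each library held 12.0% of its counts in untreated cells and 8.38% in exposed cells. Much of this difference lay in few features: that on contig 34 (1 to 2915) had 241529 reads in untreated and 100865 in exposed cells, that on contig 39 (136 to 1621) had 180346 and 82330, and the pair on contig 9 had 124412 and 6693. The features of contigs 34 and 39, 2915 and 1486 nt long, are among those whose length is not a multiple of 3. Whether they are RNA genes is not given. If they are ribosomal, their reads would also depend on how far the kit removed such RNA from each library, so their folds may not reflect transcript levels. Relative to the median feature, the feature at 136 to 1621 of contig 39 was 2.79-fold lower (2.77 to 2.81), that at 1 to 2915 of contig 34 was 3.05-fold lower (3.03 to 3.07), and that at 120033 to 120233 of contig 4 was 3.39-fold lower (3.29 to 3.50). A cluster of 5 highly expressed features on contig 2 (372131 to 375317) was between 2.24-fold and 3.17-fold lower. Against features of the same level, the log2 ratios of these 5 lay between -0.46 and 0.04. Those of the features of contigs 39, 34 and 4 were -0.27, -0.40 and -0.56. By total count the 5 lay between -0.74 and -0.24, and the features of contigs 39, 34 and 4 at -0.56, -0.68 and -0.84, all short of 2-fold. The feature at 58015 to 58323 of contig 14 was 1.81-fold lower (1.77 to 1.86), and by total count it was the only one of the 10 with the highest mean RPKM whose direction turned, to a log2 ratio of 0.07 in favour of the exposed library.

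Neighbouring features on the same strand differed together. Runs of 4 or more such neighbours, at most 100 bases apart and all at least 2-fold higher, numbered 26 and held 136 features. The corresponding runs of lower features numbered 21 and held 109. When ratios were shuffled among features of the same level, 1000 shuffles gave a median of 4 higher runs (range 0 to 11) and 11.5 lower runs (range 4 to 20). The longest lower run, 10 features at 611 to 10228 of contig 22, was 2.88-fold lower (2.82 to 2.93) over its summed reads, but its mean log2 ratio was -0.38 against features of the same level. On contig 6, 8 consecutive features (22486 to 28554, minus strand) were 4.77-fold lower (4.53 to 5.02). A run of 4 features on contig 1 (1105032 to 1110889) was 5.73-fold lower (5.57 to 5.90), and further runs on that contig, at 1528941 to 1532897 and 570271 to 583522, were 4.44-fold (4.34 to 4.54) and 3.79-fold (3.73 to 3.86) lower, but against features of the same level their mean log2 ratios were -0.93 and -0.91, short of 2-fold. The longest higher run, 9 features of contig 1 (1473021 to 1481062), lay close to the group of 3 described above and was 3.10-fold higher (2.87 to 3.36). Against features of the same level its mean log2 ratio was 0.83, and 3 of the 9 features were still 2-fold higher.

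When runs were defined anew from ratios against features of the same level, there were 4 on each side, where shuffling gave a median of 0 and at most 1. Some of these have other ends than the runs above or include features less than 2-fold from the median feature. On the higher side, 3 of the 4 lay side by side on the minus strand of contig 15, at 63037 to 65275, 65521 to 70772 and 71129 to 77850, with summed reads 3.20-fold (2.84 to 3.61), 3.05-fold (2.84 to 3.26) and 2.83-fold (2.68 to 2.99) higher. From 59413 to 77850 of that contig, all 19 kept features were on the minus strand and 18 were at least 2-fold higher, with a median RPKM of 102 in untreated and 327 in exposed cells. The other higher run was on contig 28 (40 to 4802), 2.31-fold higher (2.15 to 2.48). Over all their features, contigs 15 and 28 had median log2 ratios of 0.77 and 0.79 against their level, and the shuffles did not keep features on their contig, so they do not separate these 4 runs from a shift of the whole contig. On the lower side were the 4 features of contig 1 at 1105032, a stretch of 10 features on contig 6 (20329 to 28554), 4.09-fold lower (3.91 to 4.28), a run on contig 4 (183155 to 187927), 3.20-fold lower (3.03 to 3.39), and one on contig 3 (169194 to 173146), 2.96-fold lower (2.77 to 3.17), which follows directly on the feature 10.3-fold lower named above. Scaled to the total count, the mean log2 ratios of these runs of contigs 4 and 3 were -0.43 and -0.54, short of 2-fold.

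**Figure D2:**
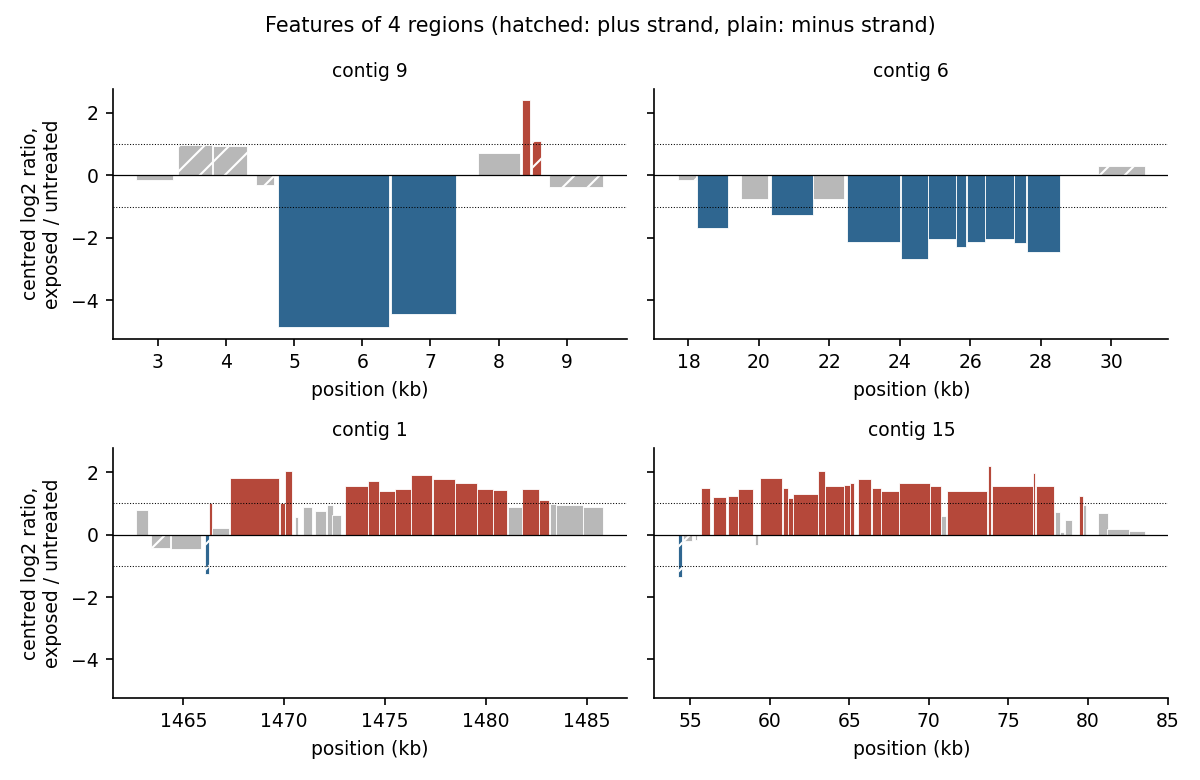
Each bar is a kept feature drawn from its start to its end along the contig (kb, horizontal), with the centred log2 ratio of exposed to untreated as its height; dotted lines mark 2-fold, hatching marks the plus strand, and red and blue mark features at least 2-fold higher and lower. The pair of contig 9 reaches -4.87 and -4.45, 9 of 10 features from 20329 to 28554 of contig 6 are at least 2-fold lower, and 12 of 17 from 1467336 to 1481062 of contig 1 and 18 of 19 from 59413 to 77850 of contig 15 are at least 2-fold higher.

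Contigs also differed as wholes. Of 29 contigs with at least 20 kept features, 11 had a median ratio above the middle 95% of 10000 random lists of the same size and expression level, 5 lay below and 13 within. The random lists draw features independently, whereas neighbours on a contig had correlated ratios, so contig medians would spread more widely than these lists by chance. The median centred log2 ratio was 0.90 on contig 15, where random lists gave -0.16 to 0.18, 0.80 on contig 29, 0.70 on contig 27, 0.63 on contig 17 and 0.61 on contig 28. Contigs 8 and 14, also above, passed the edge of their range only narrowly, at -0.14 against -0.16 and -0.61 against -0.68. Contigs 1, 2, 3, 4 and 6 lay below, and of these contig 3 was farthest from its range, at 0.44 against a lower edge of 0.60. Contigs 1, 2 and 6 passed the edge only narrowly, at -0.22 against -0.19, -0.20 against -0.16 and 0.20 against 0.23. Contig 1, with 1604 kept features and a narrow range, had a median log2 ratio of -0.01 against its level. The same median was -0.21 on contig 3, but also -0.16 and -0.19 on contigs 16 and 19, which lay within their wider ranges. The 10th percentile of reads per kb was also higher on the 11 contigs above, at 1.25 to 3.56 times that of contig 1 in untreated cells and 1.30 to 2.37 times in exposed cells. It was also above that of contig 1 in untreated cells on 7 of the 13 contigs within the range, at up to 3.49 times on contig 20.

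**Figure D3:**
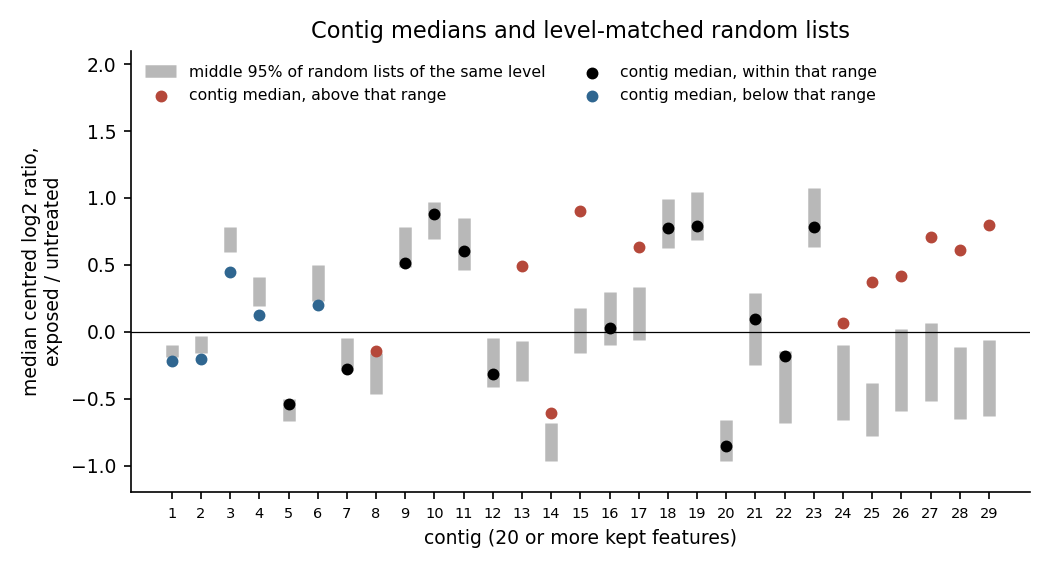
Points are the median centred log2 ratio of exposed to untreated over the kept features of each of 29 contigs, and grey bars the middle 95% of medians of 10000 random lists of features of the same size and level. Red points (11 contigs) lie above their bar, with contig 15 at 0.90, blue points (5 contigs) below and black points (13 contigs) within.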

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

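The scaling to the total count, the level-matched and floor-subtracted ratios and the limits on feature length were chosen only after the results were seen. The planned pseudocounts, filters, uncentred RPKM, trimmed-mean centre and median-of-ratios scaling left the counts within 1.5 times those reported, except that with a pseudocount of 5 RPKM 18 features were 4-fold higher in place of 32. The filter at 20 RPKM removed no kept feature. The counts changed with scaling to the same sum or total, which moved the median feature by 0.81 to 0.90 log2 units. They also changed with the level-matched centre and with floor subtraction, which left the median feature at 0. With RPKM rescaled to the same sum there were 2588 features 2-fold higher, 130 lower, 903 4-fold higher and 15 lower. Without the top 1% of features these were 2432, 149, 739 and 17, and scaled to the total count 2566, 123, 699 and 15. Centred within 20 levels of expression they were 265, 208, 17 and 14. With the 5th percentile of reads per kb subtracted as a floor they were 641, 341, 195 and 48, and with the 10th percentile 501, 301, 168 and 49. In features of 300 nt or more, 11 were 4-fold higher and 67 lower. Apart from these scalings and the fewer features kept, the cause of the changes was not tested. After the 10th percentile was subtracted, 194 of the 1096 higher features stayed above the minimum level, and 270 of the 907 lower features were still 2-fold lower. The subtracted floors differ by 2.56 to 2.75 times, so subtraction cannot bring a higher feature that stays much below its ratio, and says nothing about the stability of the higher features and runs. The 23 named features, groups and runs kept their direction in all 339 combinations with an alternative that gave a value. They had been chosen for large ratios, the smallest mean being 1.35 log2 units, for the run of contig 28. Rescaling to the same sum or total moved the median feature by at most 0.90 log2 units, so it could not turn their direction. Some runs were also chosen by the level-matched ratios themselves. The kept direction is therefore no independent check. In 15 of the 339 combinations the mean ratio came below 2-fold: 6 for the run of contig 22, 3 each for those of contig 3 at 169194 and contig 4 at 183155, and 1 each, the level-matched centre, for those of contig 1 at 1473021, 1528941 and 570271. The 2 highest features had values under 12 of 15 alternatives, since both floor subtractions and the limit of 300 nt left them out, and the run of contig 1 at 1473021 kept 2 and 1 of its 9 features with the floors subtracted. The pair of contig 9 ranged from -4.88 to -3.66 and from -4.46 to -3.24. The 10 alternatives for gene list medians were not run, since no list could be applied, and leaving out a library was not possible with 1 per group. By counting error, 366 of 1096 higher and 701 of 907 lower features had an interval wholly beyond 2-fold.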

Other observations

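All tests in this part were chosen after the results were seen. Adjacent features on the same strand, at most 100 bases apart, had like ratios: over 2132 such pairs the centred log2 ratios had a Pearson r of 0.789 across features and the same sign in 84.1%. Same-strand neighbours farther apart had an r of 0.326 (1679 pairs), and neighbours on opposite strands 0.07 (1600 pairs). Against features of the same level the order was kept, with r of 0.625, 0.342 and 0.185. Neighbours are not independent replicates, and both values come from 1 library per group. Higher features were more often short: of 1096 higher features 27.2% were under 300 nt, against 15.2% of 907 lower features and 17.9% of all kept features.

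Further features stood far from others of their level. A feature on contig 28 (17035 to 17187) was 4.19-fold higher (3.28 to 5.41), one on contig 13 (22021 to 22668) 3.82-fold higher (3.17 to 4.62), and one on contig 32 (1015 to 2247) 2.43-fold higher (2.25 to 2.63). A feature on contig 1 (161820 to 162245) was 6.29-fold lower (5.01 to 7.99). These folds are relative to the median feature. Against features of the same level the log2 ratios were 3.02, 2.17, 2.24 and -2.28 in the order named. Over all their features, contigs 28 and 13 had median log2 ratios of 0.79 and 0.57 against their level.

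The ratio between the libraries fell with the level of expression, and the tables argue against counting noise of features with few reads, because features in the lowest 20% of mean RPKM that had 200 or more reads over both libraries (671 features of 300 nt or more) still had a median centred log2 ratio of 1.02 (bootstrap 0.982 to 1.05). This bootstrap drew features as if independent, which neighbours are not, so its interval may be too narrow. A candidate explanation for part of the trend is an even background of reads, higher in the exposed library: with a floor set by the lowest 5% of features and a scale set by the highest 5%, deviations in the 18 middle levels of untreated reads per kb were at most 0.394 log2 units, against 0.695 from a straight line between the ends of the trend, which spanned 2.56, and at most 0.424 with levels of mean RPKM, where the trend spanned 2.35. The misfit was to one side, with 17 of the 18 levels above the model and a median deviation of 0.27, so whether such a background is the whole cause stays open. Floor and scale came from the ends of these same features. A smaller deviation than from a line therefore does not single out a background among causes that would bend the trend. The 5th percentile of reads per kb was 79.5 in untreated and 218 in exposed cells. Among features in the lowest 25% of the other library the spread beyond counting error was 81.3% of the mean in untreated and 24.6% in exposed cells. An even background alone predicts a small spread, and the untreated value is not small. Features low in the exposed library may have been expressed in untreated cells, so this spread does not decide. That exposure to the fungus raised low transcripts cannot be told apart from a background of reads with 1 library per group, since 97.6% of features in the lowest 20% had a ratio above 0 and both explanations predict that.

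Features of 11 contigs stood above features of the same level. A background of reads whose level differs between contigs, raised alike in both libraries, could account for part of this: with the floor of each contig taken from its untreated values, the gap between the medians of these contigs and of the 13 contigs within the range went from 0.502 log2 units to -0.0521 (bootstrap -0.219 to 0.155). Deviations of the 13 contigs within the range spread more widely under this model. They ran from -0.0562 to 0.373 with a common floor, and from -0.400 (contig 20) to 0.485 (contig 10) with each contig's untreated floor. Contigs 24 to 29, all among the 11, had only 15 to 25 features each in this model, so their floors rest on few features. The closed gap therefore does not single out such a background. This model predicted too much for contig 25, which deviated by -0.449, and left contig 15 highest among the 11, with a deviation of 0.434 (0.314 to 0.619). That was below the 0.485 of contig 10, a contig within the range, but contig 10 deviated by only 0.084 with a common floor. The 0.485 is thus a misfit of the model itself and a weak bar for contig 15. With a common floor contig 15 deviated by 0.932, and the contigs within the range by at most 0.373. A version tried earlier, with the contig's own floor in both libraries, left 0.541 (0.271 to 0.650) against at most 0.341, so whether contig 15 holds a change of its own cannot be told apart from background here. Both intervals of contig 15 are bootstraps that drew its features as if independent. Neighbours had correlated ratios, so these intervals are likely too narrow. No biological explanation, such as a mobile element or a change in copy number, was tested.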
